A study of Mus musculus with 4 samples.

How the data were processed

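RNA of 4T1 cells was hybridised to 4 arrays, 2 of the scramble control and 2 labelled as MCT-1 silencing. The design text labels the arrays of each group as independent biological replicates. Groups were taken from the titles and source names, since the description field counts from 1 to 4 over the arrays and does not tell the groups apart. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA at the gene level, and versions, options and the genome build are not given in the sources used here. The deposited values are on a log2 scale, as shown by their range from 1.29 to 19.9, and were used without a further transformation. The quartiles of the 4 columns were similar but not identical, and any step beyond RMA is not given in the sources used here. Signals of dim and of very bright probes can be compressed, and any step beyond RMA could also have changed the scale. Log2 differences there may thus not give the true size of a change. Each column was matched to its array by name, and 0 columns of per-sample values were left out.

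The table held 65956 rows. The probe table listed 32750 of them, 30604 with 1 gene symbol and 2146 with several, while 33206 were not listed and stayed unnamed. Symbols of 827 rows were updated through their gene ID with a mouse gene table of the GRCm38.p6 assembly. This gave 30142 genes, of which 355 had several rows and were represented by the row with the highest mean. Values identical to those of an earlier row were found in 1191 rows, and 3 rows had no spread within either group.

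Differences were fitted with limma 3.58.1 in R 4.3.3 on all 65956 rows (lmFit and eBayes, no trend, not robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.72 degrees of freedom. All differences are shMCT-1 minus NC. A descriptive count took an unadjusted p under 0.05 with at least 1.5-fold. The number of arrays limits the precision.

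Gene groups came from 32 lists with 808 genes, 678 of them measured, which were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry, whose direction test asks whether the members of a list move one way on balance and whose mixed test asks whether they change in either direction. The test with an estimated correlation rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. Members were also adjusted over the list alone. The lists covered the MCT-1 complex, epithelial, mesenchymal and mammary lineage genes, proteases, cytokine, NF-kappaB, IL-6, interferon, MHC class I, checkpoint, stem cell, stress, p53, cell cycle, histone, lipid, glycolysis, NRF2, EGFR, TGF-beta, ribosomal, translation, respiratory and immediate early genes, and markers of macrophages, lymphocytes, fibroblasts and endothelium.

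Genes were named by a fixed rule. It took the MCT-1 list, up to 12 genes per direction past the adjusted threshold or, as none passed, the 6 with the lowest unadjusted p per direction, up to 4 members of each list past the threshold or otherwise the 2 with the largest difference, and 8 genes of earlier work on MCT-1. The first part left out predicted genes, small RNA genes and receptor or immunoglobulin segments. Other list members named in the text, among them those that passed adjusted over the list alone, were chosen after their values were seen.

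Alternatives were a variance trend, robust moderation, no moderation, a test against a 1.2-fold change, a filter on dim rows, rows with 1 symbol, a further quantile normalisation, median centring, array weights, the replicate number as a block, the mean over a gene's rows, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other group. The fit was tested on simulated data of 65956 rows in 5 runs, each with 200 changed rows, and recovered 1.2%, 69.2%, 89.6% and 97.2% of rows changed by 1, 2, 3 and 4 log2 units, with 7.4 false calls per run.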

Results

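Gene expression was measured with whole-transcript arrays in 4T1, a mouse mammary carcinoma cell line that spreads to distant organs and serves as a model of triple-negative breast cancer. The 4 arrays fell into 2 groups of 2 replicates, which the design text labels as independent and biological. They were cells with a scramble control (NC) and cells labelled as having MCT-1 silenced under puromycin selection (shMCT-1). The values were log2 expression summaries for 65956 rows per array, with array medians of 3.68 and 3.69 in NC replicates 1 and 2 and 3.73 and 3.68 in shMCT-1 replicates 1 and 2. Whether the replicates were separate clones, or cultures of 1 clone or of a pool, is not given in the sources used here, so the SD over 2 arrays covers the spread between these samples. The number of arrays limited the precision of every comparison. The design implied 1 comparison, shMCT-1 against NC, which asked how silencing MCT-1 altered the expression profile of these cells.

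The targeted transcript came first. Mcts1, the X-linked gene (gene ID 68995) that encodes MCT-1, a partner of Denr in translation reinitiation, was measured at 7.86 and 8.05 in the NC arrays and at 7.81 and 7.89 in the shMCT-1 arrays. Its log2 difference, shMCT-1 minus NC, was -0.10 (SE 0.122, 95% interval -0.42 to 0.22, adjusted p = 0.945, limma), and the SD between replicates was 0.13 in NC and 0.061 in the arrays labelled shMCT-1 (n = 2 each). The row lay at percentile 86.0 of all rows by mean signal. A lower level was thus not detected, and the arrays are called those labelled shMCT-1 from here on. Mcts2 (gene ID 66405), an intronless copy of Mcts1 on chromosome 2, was 0.57 higher in the arrays labelled shMCT-1 (SE 0.302, adjusted p = 0.896, limma) and 0.17 higher without NC replicate 1, and whether its probes share signal with Mcts1 is not given in the sources used here. The other measured members of the MCT-1 complex and reinitiation list also did not pass, with log2 differences of 0.11 for Eif2d, 0.078 for Denr and -0.038 for Eif1a. For each of these 3 the sign turned when 1 array was left out, from -0.021 to 0.25 for Eif2d, from -0.20 to 0.35 for Denr and from -0.17 to 0.097 for Eif1a.

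Across single genes, Cldn3 had the lowest p among genes higher in the arrays labelled shMCT-1 and Krt14 among lower ones, although no gene passed after adjustment over all rows. Cldn3, a claudin of epithelial tight junctions, was 5.31 ± 0.022 (SD, n = 2) in NC and 8.91 ± 0.15 (SD, n = 2) in the arrays labelled shMCT-1, a 12.1-fold higher level. Cldn7, a further epithelial claudin, was 3.15-fold higher at 5.25 ± 0.14 against 6.90 ± 0.030 (SD, n = 2 each). Krt14, a keratin of basal epithelial cells, was 3.21-fold lower at 12.84 ± 0.12 against 11.16 ± 0.057 (SD, n = 2 each).

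The other genes with the lowest p among higher ones were Rps6ka6, a ribosomal S6 kinase of the RSK family (log2 difference 1.96, SE 0.136), Fstl3, a secreted inhibitor of activin (2.74, SE 0.204), Mall, a membrane proteolipid (1.35, SE 0.111), and Cxcl2, a neutrophil-attracting chemokine (2.30-fold, SE 0.104 log2). Among lower ones they were Padi3, a peptidylarginine deiminase of skin and hair follicles (-1.80, SE 0.130), Arhgdib (2.29-fold lower, SE 0.117 log2), and the prolactin-family genes Prl2a1 (-1.78, SE 0.154), Prl2c2 (-1.60, SE 0.159) and Prl2c5 (-1.47, SE 0.141). Prl2c2 and Prl2c5 are near-identical copies whose probes may share signal, so their separate values are uncertain. For these 12 genes, 6 in each direction, the limma p adjusted over all rows ran from 0.106 for Cldn3 to 0.882 for Prl2c2.

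**Figure D1:**
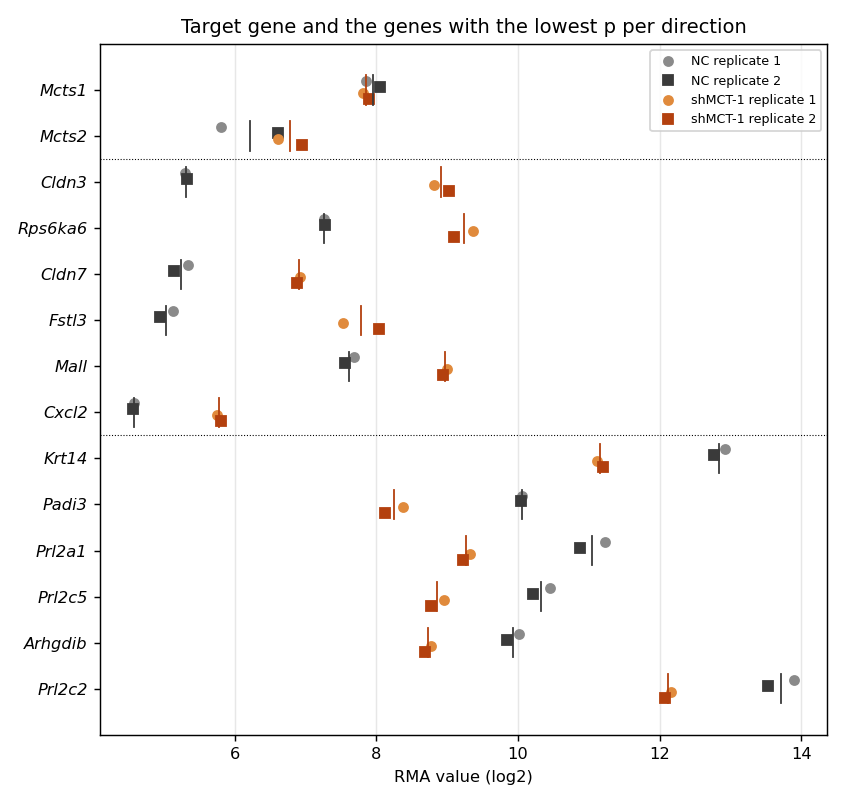
Log2 RMA values (horizontal axis) of Mcts1, Mcts2 and the 6 genes with the lowest p in each direction on each of the 4 arrays, with circles for replicate 1, squares for replicate 2 and a vertical line at each group mean. The Mcts1 points lie between 7.81 and 8.05 in both groups, whereas Cldn3 lies at 5.30 and 5.33 in NC and at 8.81 and 9.02 in the arrays labelled shMCT-1.

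With limma, 0 genes and 0 rows had an adjusted p under 0.05, and the other 14 settings of the fit also gave 0. At an unadjusted p under 0.05 there were 3698 rows, against 3298 given by chance over 65956 rows. With the replicate number as a block there were 7537 such rows, and the split by replicate number gave 5971. Without a block 393 genes also differed by at least 1.5-fold, 140 higher and 253 lower. The excess of lower genes was lost without shMCT-1 replicate 1 (230 higher, 233 lower) or shMCT-1 replicate 2 (211 and 199), and without NC replicate 2 there were 790 higher and 968 lower. The total was 130 without variance moderation, 258 when tested against a 1.2-fold change and 1757 without NC replicate 2. The 2 arrays of each group lay fully apart in 33.9% of rows, against the 33.3% that chance gives, and the smallest p that an exact two-sided permutation of 4 arrays can give is 0.333. On simulated arrays of this design, 69.2% of rows changed by 2 log2 units and 1.2% of rows changed by 1 log2 unit were recovered. These rates hold for 200 changed rows with independent errors and no shared array differences. They do not give the power of this comparison, where Cldn3 at 3.60 log2 units did not pass.

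The first principal component, with 59.3% of the variance, did not separate the groups. NC replicate 1 (-58.3) and shMCT-1 replicate 2 (48.1) were at its ends, with shMCT-1 replicate 1 (-2.59) and NC replicate 2 (12.9) between them. It did separate the replicate numbers, with both replicate 1 arrays below both replicate 2 arrays. On the second, with 23.4%, NC replicates 1 and 2 were at 11.8 and 22.5 and shMCT-1 replicates 1 and 2 at -40.4 and 6.15. NC replicate 1 differed by over 1 log2 unit from NC replicate 2 in 830 rows and from shMCT-1 replicates 1 and 2 in 609 and 1965, whereas NC replicate 2 differed by as much from these in 311 and 266 rows, and they from each other in 487. Genes at least 1 log2 unit higher in the arrays labelled shMCT-1 numbered 31, of which 28 had fully separate arrays, and genes at least that much lower numbered 132, of which 45 did. Without NC replicate 1 the counts were 29 higher and 26 lower, and without NC replicate 2 they were 147 higher and 368 lower, both chosen after seeing the data. Among the largest excesses of NC replicate 1 over the other 3 arrays were those of Usp18, which was 12.30 on NC replicate 1 and 6.91, 7.33 and 5.72 on NC replicate 2 and shMCT-1 replicates 1 and 2, of Rsad2 (11.94 against 7.53, 8.17 and 6.80) and of Oas2 (8.23 against 3.97, 4.20 and 3.77), and Ddit3 was also high there (10.39 against 6.78, 6.65 and 6.34).

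Genes of cholesterol synthesis and uptake were shifted up in the arrays labelled shMCT-1. Of 18 measured members, 17 were higher, 15 of them with fully separate arrays, and the median log2 difference was 0.61. Idi1, the isopentenyl diphosphate isomerase, was 2.41-fold higher (SE 0.268 log2), Hsd17b7, a sterol reductase, 2.30-fold (SE 0.282), Lss, the lanosterol synthase, 2.07-fold (SE 0.171) and Sqle, the squalene epoxidase, 2.02-fold (SE 0.175). Srebf2, the transcription factor that drives this pathway, was 1.54-fold higher at 10.27 ± 0.043 against 10.89 ± 0.030 (SD, n = 2 each). Dhcr7, the enzyme of the last reduction to cholesterol, was the 1 lower member at -0.25.

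Adjusted over the list alone, 13 of the 18 cholesterol genes passed, all higher, against 0 adjusted over all rows, namely Lss, Srebf2, Sqle, Cyp51, Idi1, Hsd17b7, Mvk, Sc5d, Stard4, Fdps, Nsdhl, Hmgcs1 and Insig1. The list passed limma's camera (adjusted p = 5.7e-12 over 32 lists) but not with an estimated correlation (adjusted p = 0.838 with an estimated correlation). NC replicate 1 differed from the other 3 arrays by -0.46 in the list median. The list median was 0.60 without that array and 0.64 without NC replicate 2, with 17 of 18 members higher in both, but 5 and 6 members then passed adjusted over the list alone. It was 0.41 without shMCT-1 replicate 1 and 0.83 without shMCT-1 replicate 2.

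**Figure D2:**
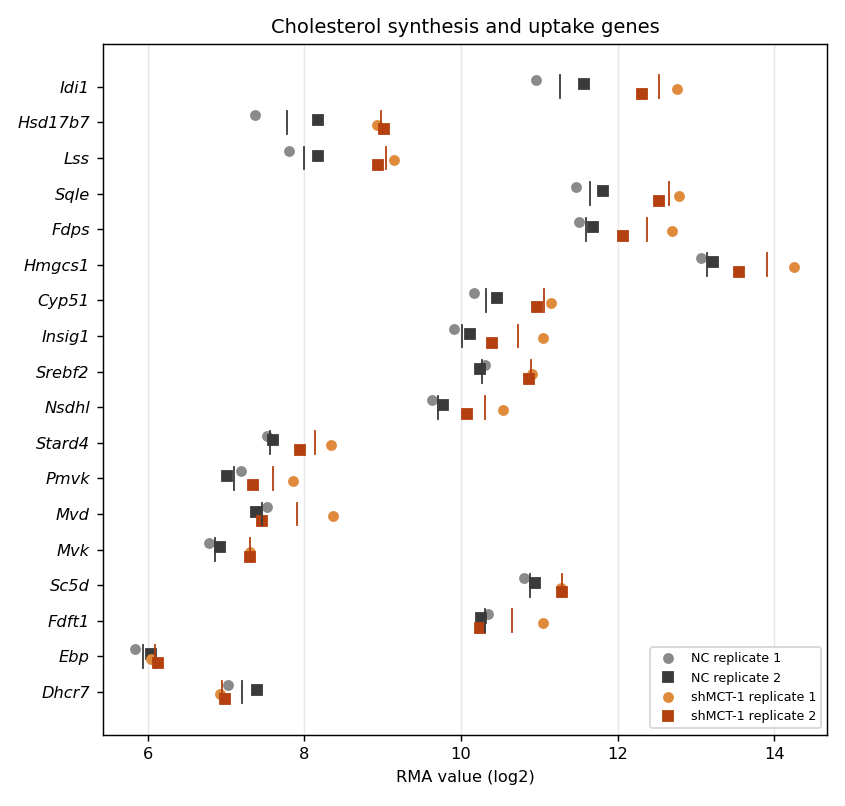
Log2 RMA values (horizontal axis) of the 18 measured genes of cholesterol synthesis and uptake on each of the 4 arrays, ordered by difference, with circles for replicate 1, squares for replicate 2 and a vertical line at each group mean. Both arrays labelled shMCT-1 lie above both NC arrays in 15 genes, and Dhcr7 is the 1 gene with a lower mean.

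Fatty acid synthesis genes were also shifted up, with 9 of 14 measured members higher and a median log2 difference of 0.19. Scd1, the stearoyl-CoA desaturase, was 2.64-fold higher at 10.19 ± 0.19 against 11.60 ± 0.28 (SD, n = 2 each) and was the 1 member that passed adjusted over the list alone (adjusted p = 0.0114, limma), against 0 over all rows. Elovl6, a fatty acid elongase, was 0.91 higher, and 0.60 without NC replicate 1, and did not pass. NC replicate 1 differed from the other 3 arrays by -0.12 in the list median, and without NC replicate 2 the members that passed adjusted over the list alone numbered 5. The list median was 0.29 without NC replicate 1, 0.10 without NC replicate 2 and 0.40 without shMCT-1 replicate 2. The list passed camera (adjusted p = 0.0262) and lost the call without shMCT-1 replicate 1 (median 0.075, adjusted p = 0.209) and with an estimated correlation (adjusted p = 0.838 with an estimated correlation).

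Epithelial and mammary lineage genes differed in both directions. Of 25 epithelial genes 8 were higher and 17 lower, and 3 passed adjusted over the list alone, Cldn3 (adjusted p = 4.01e-05, limma) and Cldn7 (adjusted p = 0.000699) higher and Krt19, a luminal keratin, lower (adjusted p = 0.0163), against 0 over all rows. Of 18 basal and luminal mammary markers, 6 were higher and 12 lower, and Krt14 (-1.68), Krt19 (-1.14) and Krt17 (-0.75) passed adjusted over the list alone, against 0 over all rows. The keratins Krt14 and Krt17 belong to the basal layer and Krt19 to luminal cells, so the members that passed came from both sides of the list. Cdh1, the epithelial cadherin, was -0.30 and did not pass. NC replicate 1 differed from the other 3 arrays by 0.21 in the median of the epithelial list and by 0.00999 in that of the mammary list.

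The mammary marker list passed camera as lower (adjusted p = 0.0366, median -0.045), and the adjusted p was 0.838 with an estimated correlation. It lost the call after a further quantile normalisation (adjusted p = 0.0511), median centring (0.0501), and without NC replicate 2 (0.0683), shMCT-1 replicate 1 (0.102) or shMCT-1 replicate 2 (0.146), and without NC replicate 1 the members passing adjusted over the list alone numbered 1. Its median was -0.080 without NC replicate 1 and -0.10 without shMCT-1 replicate 2. The epithelial list did not pass camera (adjusted p = 0.322), and its median of -0.050 and camera's downward direction differed in sign from its mean of 0.056 and from fry's direction. With 1 array left out that median was further from 0, at -0.091 without NC replicate 1, -0.17 without NC replicate 2 and -0.073 and -0.10 without shMCT-1 replicates 1 and 2. Of mesenchymal genes, 13 of 24 were higher (median 0.013, adjusted p = 0.916, camera). Sparc, a matrix glycoprotein, was at -0.78, and from -1.07 to -0.49 with 1 array left out. Tnc, a matrix tenascin, was at 0.65 (0.31 without NC replicate 1), and neither gene passed. NC replicate 1 differed from the other arrays by -0.028 in the list median.

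Genes of proteases and invasion were shifted down, with 19 of 24 measured members lower and a median log2 difference of -0.13, which was -0.22 without NC replicate 1 and -0.31 without shMCT-1 replicate 2. The membrane-type metalloprotease Mmp14 (-0.62, SE 0.112), the gelatinase Mmp9 (-0.57, SE 0.113) and the sheddase Adam8 (-0.48, SE 0.103) passed adjusted over the list alone, each with an adjusted p of 0.0499 in limma, against 0 over all rows. The list also holds inhibitors of proteases, and the measured ones were among the lower members. They were Timp1 (-0.10), Timp2 (-0.33), Timp3 (-0.030) and Serpinb2 (-0.40), so the list shift does not separate proteases from their inhibitors. Mmp14, Plau (-0.47) and Ctsb (-0.41) lie on chromosome 14, whose genes had a median difference of -0.17. The members with the largest differences did not pass. The stromelysin Mmp3 was at 1.24 (SE 1.11) and turned to -0.068 without NC replicate 1, and Mmp11 was at -0.85 (SE 0.439) and at -0.24 without that array. In the list median, NC replicate 1 was 0.054 above the other 3 arrays. The list passed camera (adjusted p = 0.00167), not without shMCT-1 replicate 1 (0.0736) and not with an estimated correlation (adjusted p = 0.838 with an estimated correlation), and 0 members passed adjusted over the list alone when either NC array was left out.

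Interferon-stimulated genes were high on NC replicate 1, and their shift depended on it. All 35 measured members had a lower mean and the median log2 difference was -1.18, but 3 had fully separate arrays. NC replicate 1 lay 2.55 above the mean of the other 3 arrays in the list median, and against NC replicate 2 alone the median difference was 0.018, with 18 members higher and 17 lower. Taken singly against NC replicate 2, a comparison chosen after seeing the data, shMCT-1 replicate 1 was higher in 32 members (median 0.39) and shMCT-1 replicate 2 lower in 33 (median -0.28). Usp18, which removes ISG15 from proteins, and Rsad2, the antiviral protein viperin, had differences of -3.08 (SE 1.83) and -2.25 (SE 1.51), and of -0.39 and -0.042 without NC replicate 1. The list passed camera (adjusted p = 4.29e-08, and 6.56e-14 with the replicate number as a block), not without NC replicate 1 (adjusted p = 0.937) and not with an estimated correlation (adjusted p = 0.902 with an estimated correlation). Adjusted over the list alone 0 members passed, as over all rows, and 33 did so without NC replicate 2.

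MHC class I antigen presentation genes followed the same array, with NC replicate 1 0.66 above the other 3 in the list median. Of 17 measured members 15 were lower, the median log2 difference was -0.17, and 0 passed over the list alone or over all rows. Erap1, the peptide-trimming aminopeptidase, was at -0.79 (SE 0.245) and the immunoproteasome subunit Psmb10 at -0.77 (SE 0.370), and without NC replicate 1 they were at -0.45 and -0.23. The list passed camera (adjusted p = 0.0262), and without NC replicate 1 its median was 0.10 (adjusted p = 0.346). The call was also lost after quantile normalisation (0.0588), median centring (0.0501), without shMCT-1 replicate 1 (0.0693) or shMCT-1 replicate 2 (0.276), and with an estimated correlation (adjusted p = 0.902 with an estimated correlation).

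Cytosolic ribosomal protein genes were shifted up by a small amount, with 21 of 25 measured members higher and a median of 0.11. Rpl7a (0.33, SE 0.123) and Rps9 (0.33, SE 0.145) had the largest differences, at 0.23 and 0.21 without NC replicate 1. Over the list alone or over all rows 0 members passed. In the list median, the difference of NC replicate 1 from the other 3 arrays was -0.20. The list passed camera (adjusted p = 0.00371), not without NC replicate 1 (median 0.027, adjusted p = 0.346), not without shMCT-1 replicate 2 (adjusted p = 0.214) and not with an estimated correlation (adjusted p = 0.902 with an estimated correlation). The median was 0.21 without NC replicate 2 and 0.17 without shMCT-1 replicate 1. In all, 7 of the 32 lists passed camera with its preset correlation. With an estimated correlation or in fry's test of direction 0 passed. The lowest unadjusted camera p with an estimated correlation was 0.0525, for proteases and invasion. Their estimated correlation of -0.035 was below the preset 0.01, where the unadjusted camera p was 0.000157. The estimate was 0.99 for interferon-stimulated genes, 0.75 for MHC class I genes, 0.57 for ribosomal protein genes and 0.46 for cholesterol genes. In these lists the preset 0.01 was far below the estimate, so their camera p at the preset correlation may be too small. The estimate was 0.024 for fatty acid synthesis genes and -0.0043 for mammary markers. The estimated test rests on 2 residual degrees of freedom, so losing a call there does not show that gene correlation explains it. Of the other splits of the arrays, that by replicate number gave 10 lists at the preset correlation and the crossed one 7, as many as the groups.

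**Figure D3:**
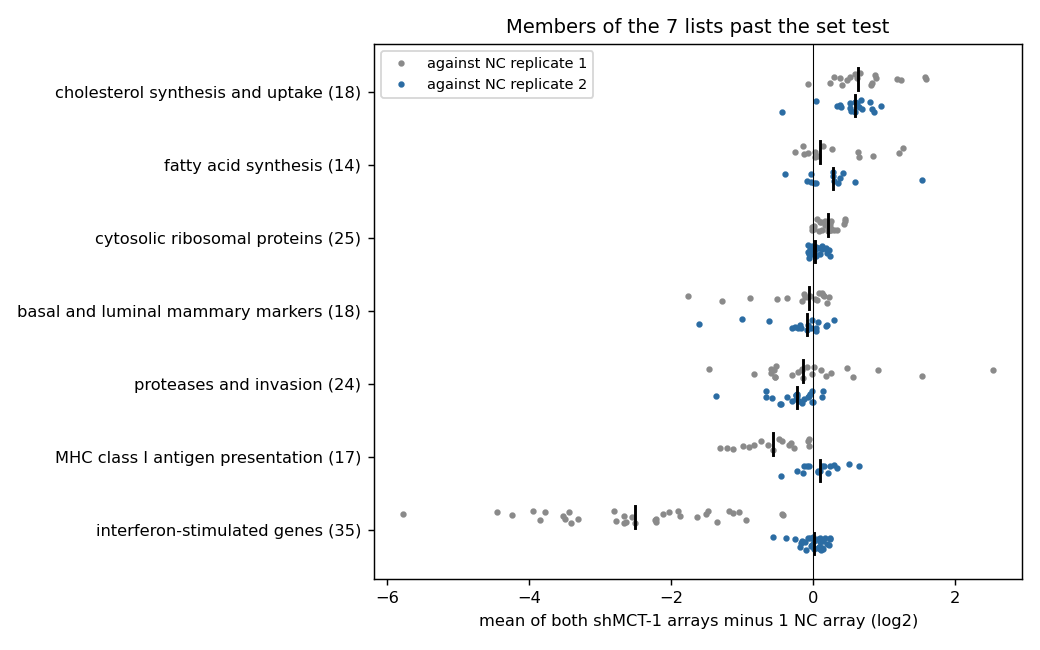
Log2 difference between the mean of both arrays labelled shMCT-1 and each NC array (horizontal axis) for every measured member of the 7 lists that passed camera, with the number of members in brackets, grey points against NC replicate 1, blue points against NC replicate 2 and black bars at the medians. Interferon-stimulated genes have a median of -2.50 against NC replicate 1 and 0.018 against NC replicate 2, whereas cholesterol genes have medians of 0.64 and 0.60.

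Inflammatory and stress genes that passed adjusted over the list alone were few and went both ways. Among 37 chemokines, cytokines and growth factors of myeloid cells, Cxcl2 was higher (adjusted p = 0.00445, limma), at a mean of 4.58 in NC and 5.78 in the arrays labelled shMCT-1. Of related chemokines, Cxcl3 was at 1.16 and the brighter Cxcl1 and Cxcl5 were at -0.056 and 0.28, and none of them passed. S100a8, a calcium-binding protein of myeloid cells, was -0.76 (adjusted p = 0.0376, limma). It was near the array medians in the arrays labelled shMCT-1, at 3.65 and 3.61, and S100a9 was at -0.016. Ccl5 was -1.21, and -0.31 without NC replicate 1, and did not pass. Among 19 NF-kappaB targets, Tnfaip2 (-0.64) and Nfkbiz (-0.78), an atypical I-kappaB protein, passed, both with an adjusted p of 0.0263. Among 31 ATF4 targets, Cth, the cystathionine gamma-lyase, passed at 0.90 (adjusted p = 0.013). The count over all rows was 0 for these 3 lists, whose members passing over the list alone numbered 1, 0 and 2 without NC replicate 1 and 7, 6 and 4 without NC replicate 2. Their medians of -0.023, 0.026 and -0.042 did not pass camera (adjusted p = 0.547, 0.803 and 0.547), and NC replicate 1 differed from the other arrays by 0.029, -0.041 and 0.35. Without NC replicate 1 the ATF4 list passed as higher (median 0.20, adjusted p = 5.98e-05), and without NC replicate 2 as lower (median -0.34, adjusted p = 4.06e-07). Ddit3 and Ddit4 of that list were at -2.09 (SE 1.18) and -0.97 (SE 0.962), and without NC replicate 1 they were at -0.28 and 0.23.

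Lists on proliferation were slightly higher without passing. With the replicate number as a block the DNA replication and G1/S list passed camera (adjusted p = 0.00983). DNA replication and G1/S genes had a median of 0.19 with 20 of 28 members higher (adjusted p = 0.0994, camera), and mitosis and G2/M genes a median of 0.081 with 22 of 29 higher (adjusted p = 0.0994). Mcm3, a subunit of the replicative helicase, was at 0.61 and Dut, the dUTPase, at 0.57, and of the mitotic genes Cdc25c was at -0.55 and Kif23 at 0.41, with none passing. NC replicate 1 differed from the other 3 arrays by -0.38 and -0.090 in these medians, and the first list passed without NC replicate 2 (median 0.37, adjusted p = 0.000254) and without shMCT-1 replicate 1 (0.29, 0.00691), but had a median of 0.0064 without NC replicate 1 (adjusted p = 0.937) and 0.034 without shMCT-1 replicate 2 (0.904). The median of the mitotic list was 0.037 without NC replicate 1, 0.15 without NC replicate 2 and 0.13 without shMCT-1 replicate 1. Without NC replicate 1, Mcm3 was at 0.29, Dut at 0.35 and Kif23 at 0.22. Replication-dependent histones (6 measured, median 0.13, adjusted p = 0.25) and p53 targets (median -0.073, adjusted p = 0.25) did not pass, with H2ac20 at 0.50, H1f1 at 0.37, Fas at 1.13 and Gadd45a at -0.52, and without NC replicate 1 Fas was at 0.33, Gadd45a at 0.31, H2ac20 at 0.27 and H1f1 at 0.059. Without that array the histone median was 0.058 and the p53 median -0.0072, and it differed from the others by -0.32 and 0.12 in these medians. The histone median was 0.30 without NC replicate 2, and the p53 median was -0.018 and -0.14 without shMCT-1 replicates 1 and 2.

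Signalling lists did not pass camera either, except the IL-6 list with the replicate number as a block (adjusted p = 0.0423). The median was -0.13 for IL-6, JAK and STAT3 signalling (adjusted p = 0.0994), with the kinase Pim1 at -0.65 and the oncostatin M receptor Osmr at -0.45. It was -0.23 for the unfolded protein response (adjusted p = 0.0764), with Herpud1 at -1.16 and Dnajb9 at -0.46. The medians without NC replicate 1 were -0.024 and -0.041 (adjusted p = 0.937 and 0.567), without NC replicate 2 both lists passed as lower (medians -0.21 and -0.31, adjusted p = 0.00271 and 0.00237), and NC replicate 1 was 0.16 and 0.23 above the other arrays in them. For immune checkpoint ligands and related surface molecules (median -0.057, adjusted p = 0.185, camera), Lgals9 was at -1.51 and the receptor Fas at 1.13. In the median of that list NC replicate 1 was 0.12 above the other arrays, and the list median was -0.15 without NC replicate 2. For EGFR, its ligands and MAPK feedback (0.027, adjusted p = 0.719), Fosl1 was at 0.94 and Btc at -0.89, and for TGF-beta and YAP targets (0.0069, adjusted p = 0.724), Thbs1 was at 0.88 and Id2 at -0.58. Without NC replicate 1 the sign turned for Pim1 (0.30), Herpud1 (0.018) and Lgals9 (0.0098), and Osmr was at -0.12, Dnajb9 at -0.19, Fosl1 at 0.47, Thbs1 at 1.45 and Id2 at -0.0083. Immediate early genes had a median of 0.059 (adjusted p = 0.206), and of 0.10 without shMCT-1 replicate 1, with the phosphatase Dusp1 at 0.68 and the nuclear receptor Nr4a1 at 0.58. NC replicate 1 differed from the other arrays by -0.15, 0.022 and -0.067 in the medians of these last 3 lists.

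Of the remaining metabolic and translation lists, medians were 0.0089 for glycolysis and hypoxia (adjusted p = 0.877, camera), 0.027 for NRF2 targets (0.916), 0.015 for oxidative phosphorylation (0.824), 0.075 for translation factors and mTORC1 regulators (0.724), 0.016 for stem cell genes (0.724) and 0.078 for the MCT-1 complex (0.802). The translation factor median was 0.030 without NC replicate 1 and 0.012 without shMCT-1 replicate 2. The NRF2 list passed without NC replicate 1 (median 0.077, adjusted p = 0.0253). Car9, the hypoxia-induced carbonic anhydrase, was at -1.01 and Aldoc at 0.79, Nqo1 at 0.72 and Hmox1 at -0.60, Cycs at 0.57 and Ndufa4 at 0.47, Eif4ebp1 at -0.53 and Eif2ak2 at -0.47, and Abcb1b at 0.74 and Id3 at -0.57. Without NC replicate 1, Hmox1 and Eif2ak2 turned to 0.039 and 0.24, and Nqo1 was at 1.40, Cycs at 0.33, Eif4ebp1 at -0.20 and Abcb1b at 0.24. That array differed from the other arrays by -0.18 in the MCT-1 complex median to 0.22 in the NRF2 median. With 1 array left out Aldoc ranged from 0.45 to 1.13 and Car9 from -1.32 to -0.70. The mean or camera's direction differed in sign from the median in the lists of mesenchymal genes, NF-kappaB targets, stem cell genes, glycolysis and hypoxia, EGFR, TGF-beta and YAP targets, translation factors and macrophage markers. In these metabolic and translation lists and those on mesenchymal genes, signalling, proliferation and other cell types, 0 members passed over the list alone or over all rows.

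Markers of other cell types did not pass camera, and most lay near the array background. Median row percentiles were 37.8 for macrophage and monocyte markers, 38.0 for lymphocyte markers, 28.1 for fibroblast markers and 35.4 for endothelial markers. Flt1 (percentile 78.2), Ly6c2 (79.3) and Csf1r (72.4) were among the brighter ones. The median log2 differences were 0.0056 (adjusted p = 0.877), -0.011 (0.858), -0.0039 (0.724) and -0.023 (0.25). The largest differences were those of the monocyte marker Ly6c2 (-1.96, SE 0.796) and of Csf1r (-0.47), of Cd2 (-0.19) and Cd3g (0.18), of Lum (-0.18) and Dcn (-0.077), and of Cdh5 (-0.43) and Flt1 (-0.30). All of these genes except Csf1r had fully separate arrays, but they were picked for the largest differences in their lists. Over all rows 33.9% were fully separate, and Dcn was so at 2.99 on NC replicate 2 against 2.97 on shMCT-1 replicate 1. The endothelial list passed fry's mixed test (adjusted p = 0.0102). In Ly6c2 the excess was on NC replicate 1, at 8.41 against 5.99, 5.32 and 5.16 on NC replicate 2 and shMCT-1 replicates 1 and 2, and without that array Ly6c2 was at -0.75 and Csf1r at 0.26. The medians of NC replicate 1 minus the other arrays were -0.0042, 0.042, -0.013 and 0.067 in these 4 lists.

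The genes tied to MCT-1 in earlier work did not pass. Egfr was -0.46 (SE 0.105, unadjusted p = 0.00818, adjusted p = 0.882, limma), with separate arrays at 6.68 and 6.61 in NC and 6.19 and 6.18 in those labelled shMCT-1. Ccl2, a monocyte chemokine, was -0.45 (SE 0.214), Cd274, which encodes PD-L1, -0.21 (SE 0.237), Il6ra -0.16 (SE 0.125) and Sod2 0.23 (SE 0.118). Il6 lay near the array background at percentile 18.5 with -0.020, Yy1 was at -0.035, and Cd44 was at 0.0049, which turned to -0.094 after quantile normalisation and to -0.021 after median centring. Without NC replicate 1 the difference was 0.11 for Cd274, 0.078 for Il6, -0.17 for Ccl2, -0.24 for Il6ra, 0.14 for Sod2 and -0.26 for Cd44.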

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

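The counts of list members and of genes over 1 log2 unit without an NC array, of genes in the split by replicate number with 1 array left out, and of members of single arrays against NC replicate 2, were chosen after seeing the data. The count of genes with an adjusted p under 0.05 was 0 under all 14 alternatives. Deviations from the group means correlated between the 2 replicate 1 arrays (0.419, and 0.73 over rows with a mean of at least 6). A shared replicate effect is thus possible, but 2 pairs do not establish pairing. With the replicate number as a block, 0 genes passed, 734 genes reached p under 0.05 and 1.5-fold against 393, and the IL-6 (adjusted p = 0.0423) and G1/S lists (0.00983) were added to the 7 called, with no other call changed. The 393 genes became 130 without moderation, 258 against a 1.2-fold change, and 337 to 1757 with 1 array left out. The 7 list calls became 0 with an estimated correlation, 0 in fry's direction test, 3 in its mixed test (epithelial 0.0102, endothelial 0.0102, mammary 0.0428) and 4 to 11 with 1 array left out. Mcts1 stayed below 0 throughout, from -0.20 to -0.0095 with 1 array left out. Cldn3 ranged from 3.50 to 3.71, with an adjusted p from 0.06 to 0.999. The median over all rows was 0.024 as deposited, 0.0021 after quantile normalisation and -0.0021 after centring.

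Signs turned as follows, and the cause was not tested. Cd44 went to -0.094 with quantile normalisation and to -0.021 with median centring. With 1 array left out, log2 differences ranged from -0.021 to 0.25 for Eif2d, from -0.20 to 0.35 for Denr, from -0.17 to 0.097 for Eif1a, from -0.068 to 2.54 for Mmp3, from -1.59 to 0.30 for Pim1, from -3.02 to 0.0098 for Lgals9, from -2.16 to 0.23 for Ddit4, from -2.34 to 0.018 for Herpud1, from -1.35 to 0.31 for Gadd45a, from -1.23 to 0.039 for Hmox1, from -1.18 to 0.24 for Eif2ak2, from -1.202 to 0.26 for Csf1r, from -0.54 to 0.11 for Cd274, from -0.12 to 0.078 for Il6, from -0.083 to 0.012 for Yy1 and from -0.26 to 0.26 for Cd44. List medians changed sign in 18 of 32 lists with 1 array left out, ranging from -0.15 to 0.25 for the MCT-1 complex, from -0.033 to 0.047 for mesenchymal genes, from -0.083 to 0.043 for chemokines and cytokines, from -0.029 to 0.14 for NF-kappaB targets, from -2.50 to 0.018 for interferon-stimulated genes, from -0.56 to 0.10 for MHC class I genes, from -0.15 to 0.026 for checkpoint ligands, from -0.099 to 0.029 for stem cell genes, from -0.34 to 0.20 for ATF4 targets, from -0.15 to 0.047 for glycolysis and hypoxia, from -0.071 to 0.077 for NRF2 targets, from -0.094 to 0.13 for EGFR and MAPK feedback, from -0.018 to 0.029 for TGF-beta and YAP targets, from -0.040 to 0.083 for oxidative phosphorylation, from -0.033 to 0.029 for macrophage markers, from -0.049 to 0.057 for lymphocyte markers, from -0.070 to 0.044 for fibroblast markers and from -0.077 to 0.0026 for endothelial markers. Quantile normalisation turned the median to -0.0074 for mesenchymal genes, -4.5e-05 for NF-kappaB targets, -0.024 for stem cell genes, -0.016 for glycolysis and hypoxia, -0.028 for EGFR and MAPK feedback, -0.014 for TGF-beta and YAP targets, -0.028 for oxidative phosphorylation, -0.00015 for immediate early genes and -0.0010 for macrophage markers. Median centring turned the median to -0.013 for mesenchymal genes, -0.00024 for NF-kappaB targets, -0.010 for stem cell genes, -0.017 for glycolysis and hypoxia, -0.019 for TGF-beta and YAP targets, -0.011 for oxidative phosphorylation and -0.020 for macrophage markers. Leaving out dim genes turned the median to -0.032 for mesenchymal genes, -0.021 for stem cell genes, -0.0014 for glycolysis and hypoxia and -0.19 for macrophage markers. Among comparisons of a result with an alternative, 1566 kept direction and side of the threshold and 70 changed sign. A further 48 lost the threshold or shrank, and 23 gained it or grew. Much of the 1566 was fixed beforehand, so it does not measure robustness. The variance trend, robust moderation, no moderation and the test against a 1.2-fold change leave a gene's log2 difference as it was. No gene passed over all rows in any setting, so single genes stayed on the same side of that threshold. Near the array background, as for Il6 and most markers of other cell types, small differences are compressed, and a lower signal limits what can be seen.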

Other observations

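The tests of Mcts1, of copy number and of other groupings of the arrays, with and without each array or with an estimated correlation, were chosen after the result was seen, as were the gene families and the chromosome comparison. Within the claudins, Cldn3 and Cldn7 were higher in the arrays labelled shMCT-1, whereas Cldn4, the brightest claudin measured here, was at 17.21, 16.73, 16.86 and 16.36 on NC replicates 1 and 2 and shMCT-1 replicates 1 and 2. Cldn1 was -1.79 (SE 0.748, adjusted p = 0.882, limma), with 9.20 on NC replicate 1 against 7.20, 6.95 and 5.87 on the others. Among keratins, Krt16, a keratin of stressed epidermis, was -1.29 (SE 0.275), beside the lower Krt14, Krt17 and Krt19, while Krt7, Krt8 and Krt18 were at -0.050, -0.028 and -0.022. The prolactin-family gene Prl2c1 was -0.74 (SE 0.132), and Prl3d2 and Prl8a9 were at 0.039 and -0.15. None of these genes passed after adjustment over all rows.

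Genes outside the fixed interferon list were high on NC replicate 1 too. Gbp4, Gbp7 and Gbp9, which are interferon-induced GTPases, were 3.20, 3.31 and 3.30 above the mean of the other 3 arrays. Nos2, the inducible nitric oxide synthase, was 2.93 above it and Trim30a 3.92. Comparing replicate number 2 with 1 over both groups, 10 lists passed camera at its preset correlation and 0 with an estimated one (lowest adjusted p = 0.67). At the preset one, interferon-stimulated genes had the largest median (-1.61, adjusted p = 2.23e-11), followed by MHC class I genes (-0.45, 8.5e-06), and NC replicate 1 is 1 of the arrays with number 1. ATF4 targets (-0.22, 3.71e-05) and glycolysis and hypoxia genes (-0.19, 0.00391) were lower in number 2, and DNA replication and G1/S genes were higher (0.26, 1.21e-05).

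Interferon-stimulated genes were 2.55 higher (median, 95% interval 1.89 to 2.86) on NC replicate 1 than the mean of the other 3 arrays, in 33 of 35 members by over 0.5. Immune cells in that culture were argued against, since the macrophage and monocyte markers had a median of -0.0042 (95% interval -0.067 to 0.063), and the abundant Lyz2, Tyrobp and Ptprc were at 2.91, 2.63 and 3.41 on that array, although Ly6c2, Csf1r, Cd68 and Arg1 were over 0.5 higher there. A scaling offset of the array was argued against by 674 genes matched on expression, with a median of -0.024. An interferon response of the tumour cells in that culture remains open as a hypothesis and was not tested.

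Mcts1 was not detectably lower in the arrays labelled shMCT-1. A signal at the floor or ceiling of the array was argued against by its percentile of 86.0. The largest Mcts1 difference over the 3 splits of the arrays was 0.14, with an interval up to 0.43. Exchanged labels would show in another split only if this row reports the silencing, so the test cannot decide them. Probes shared with Mcts2, whose row differed by 0.57 and by 0.17 without NC replicate 1, could still mask a lower Mcts1 signal, and no probe sequences were used here to decide it. Weak silencing, or silencing that these probes do not see, stays open and was not tested.

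Whole chromosomes differed between the groups by small amounts. Over 7711 protein-coding genes on 20 chromosomes, median log2 differences ran from -0.19 on chromosome 8 (445 genes, 18% of them higher) and -0.17 on chromosome 14 to 0.13 on chromosome 2 and 0.16 on chromosome 15 (303 genes, 76.2% higher), and the SD of the chromosome medians was 0.103, against a mean of 0.0145 when genes were permuted over chromosomes (permutation p = 5e-04, the smallest that 2000 permutations can give). Within the groups the SD was 0.0238 between the NC arrays (permutation p = 0.0695) and 0.0195 between the arrays labelled shMCT-1 (permutation p = 0.0175). A permutation p under 0.05 was thus also reached within a group, so it does not by itself mark a difference between the groups. Array noise that follows position was argued against by the size of the SDs. The smallest of the 4 SDs between arrays of different groups was 4.27 times the larger SD within a group. A trend with intensity was argued against too, as its removal left 101.7% of the SD. A difference in copy number between the cell populations, as selection of cells could leave, may account for this pattern, as a hypothesis found and tested on the same data. It cannot be separated from silencing of MCT-1 by this design, since both arrays of a group share it and the labels do not say whether they come from 1 clone, and genes on these chromosomes may carry part of it.

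The 393 genes at an unadjusted p under 0.05 and 1.5-fold compare with 770 when the arrays were split by replicate number, the highest of the other splits, so that 2 of the 3 splits gave as many. With 3 splits a share under 0.05 cannot be reached. The split by replicate number gave 693, 998, 2204 and 489 genes without NC replicates 1 and 2 and shMCT-1 replicates 1 and 2, each time with 1 array against 2, so these counts do not show which arrays the 770 rest on. With the replicate number as a block the group comparison gave 734 genes.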
